A study of Arabidopsis thaliana with 10 samples.

How the data were processed

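The series profiled RNA-protein contacts and RNA folding in nuclei of 10-day-old *Arabidopsis thaliana* Col-0 seedlings that carry a tagged nuclear envelope protein, so that nuclei can be pulled from a lysate. In protein interaction profile sequencing (PIP-seq), nuclei fixed with 1% formaldehyde are lysed and the lysate is divided. One RNase cuts paired RNA (dsRNase) and the other unpaired RNA (ssRNase), and each acts either while proteins are still bound or after they have been removed. RNA that survives only with proteins bound is called a protein-protected site (PPS). The 8 PIP-seq libraries comprise replicates 3 and 4 of the 4 combinations of RNase and protein state. Another 2 libraries (replicates 1 and 2) hold nuclear RNA normalized with a duplex-specific nuclease (DSN). The labels do not say whether replicates came from separate cultures, so spreads between replicates may be technical.

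Per the submitters' processing notes, adapters were trimmed with cutadapt 1.2.1, reads were aligned with TopHat2 2.0.10 to TAIR10, and bedtools was used. The PPS lists give the authors' own score for each site. Per the file names they were called with CSAR at a false discovery rate of 5%, for each RNase and replicate apart, on the 5 nuclear chromosomes. Lists were compared by position, and scores were used only to rank sites within a list. The deposited merged list joins the 4 lists into 40131 sites. Of its 66846 member sites, 66846 matched the per-replicate lists in name and score. A twin of the merged list has the RNase names exchanged, with 8 matches as deposited and 66846 after exchanging the names back. The names of the per-replicate lists were used throughout, and which naming is right was not settled from the data. If these are the wrong ones, every value given for 1 RNase belongs to the other.

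The structure files give the authors' deposited score for each nucleotide of mature mRNAs, primary mRNAs and the region around the cleavage site. Per the labels these pool the protein-removed libraries of both replicates and both RNases, so there are no replicates. Transcripts are listed with at least 100 reads, and cleavage regions with at least 10. The score has no fixed range and rises with reads named double-stranded over reads named single-stranded (Pearson r = 0.88 across 9543 mature mRNAs, which are not independent replicates). The file headers do not say which RNase gave which reads. The intron files hold deposited counts of unspliced and spliced reads for the first and last constitutive intron of 21132 genes, of which 21131 are in both tables. A deposited column headed as a ratio is, from the values, the fraction of unspliced reads, written as 0 where an intron has no reads.

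The lowest-numbered transcript model stood for each gene, giving 12329 genes with a primary and 9554 with a mature transcript. Strands were taken from the intron tables and were known for 11198 genes (5606 plus, 5592 minus). In the 1131 genes without a known strand, PPSs of either strand were counted, so antisense sites can be included. Exon positions could be worked out for 1462 genes, those whose first and last introns account for the whole difference between primary and mature length. Transcript parts were compared in these genes. The expected distribution came from 100 joint rotations of a gene's PPSs within its primary transcript, so the smallest two-sided p is 0.0198. With 2 lists against 2, an exact two-sided permutation test cannot go below 0.333. Landmarks were windows of 20 nt on each side, and splice sites were those of first and last constitutive introns alone. Structure inside PPSs was set against flanks of 50 nt. Structure differences carry a 95% bootstrap interval over sites or transcripts (1000 resamples), and a difference was called when it excluded 0. These intervals cover the spread between sites or transcripts alone.

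The PPS load of a gene list was the median PPS nucleotides per kb of mature transcript over its members. Sites in introns count in the numerator, so values can pass 1000. It was placed among 10000 random lists matched on bins of length and of read depth (10 bins each), with Benjamini-Hochberg adjustment over 10 lists. For introns, the value was log2 of unspliced over spliced reads with a pseudocount of 1, in place of the deposited fraction, to fit the planned pseudocount. The median difference was the planned statistic, and edgeR's quasi-likelihood test was added because the tables hold counts. Its 8 columns are the 2 read kinds in 2 introns of 2 replicates, with 1 library size per replicate and a minimum of 10 reads per gene. Columns of a replicate come from the same library. Introns with and without a PPS were compared with 10000 permutations within length bins, among introns with at least 1 read. That read filter was set when the comparison was coded and is not in the design fixed beforehand.

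On simulated data, the edgeR model recovered 0% of 200 genes changed 4-fold and 29% of 200 changed 16-fold among 2585 genes. The list test called 7 of 100 random lists at an unadjusted threshold of 0.05, and 40 of 100 lists of 15 genes raised by 60 nt per kb. In the transcript part test, 0 parts passed without a simulated preference and the raised part was found.

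The designs, gene lists and the rule for named genes were fixed before the data were examined. The rule takes the 10 genes per RNase with most PPSs in both replicates, the 2 members of each gene list with most merged PPS nucleotides and any that stand out, and the 10 highest and 10 lowest mature mRNAs by mean structure score. It also takes the 5 highest genes of each intron table, the 5 largest differences in each direction, the 5 longest merged PPSs, and RANGAP1, UBQ10, ACT2 and GRP7. Symbols came from a RefSeq gene table of assembly TAIR10.1, which matched all 223 locus IDs needed. Positions are 1-based on TAIR10 as deposited. Alternatives covered score thresholds, overlap rules, flanks, windows, expected distributions, filters, pseudocounts, matching and each replicate left out. The numbers 3 and 4 are shared between groups, but no label says that they mark a shared batch. Hexamer enrichment was not run, since no genome sequence was used here. Noncoding RNA classes, and parts by any transcript model, were not analysed here. Python 3.11.15 with numpy, pandas and scipy, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0 were used.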

Results

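The data comprised 4 PPS lists, 2 for each RNase, with a merged list, per-nucleotide structure scores pooled over the protein-removed libraries, and intron read counts from 2 nuclear RNA libraries. Total reads of the PIP-seq libraries are not given in the files used, so the depth behind each list is unknown. The scored primary transcripts had between 100 and 734040 reads. In genes with 2 different introns, the nuclear RNA libraries had 22116 and 20801 reads on first introns in replicates 1 and 2, and 22154 and 20525 on last introns.

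How much nuclear RNA was protected, and in which genes, was compared between the RNases. The dsRNase lists held 28101 ± 1093 PPSs (SD, n = 2) and the ssRNase lists 5322 ± 556 (SD, n = 2), a ratio of 5.30 ± 0.35. A PPS was found in 44.3% of the 12329 genes with dsRNase and in 18.5% with ssRNase. Median lengths were 56.5 and 52 nt. The most deeply read 20% of genes held 72.1% and 72.2% of dsRNase PPSs in replicates 3 and 4, and 83.1% and 76.2% of ssRNase PPSs.

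The genes with most dsRNase PPSs present in both replicates were AT1G18270 (49 sites, chromosome 1, 6283412 to 6293871), the callose synthase genes GSL8 (40) and CALS1 (30), AT5G40450 (38), AT1G48090 (34), NAI2 (31), the actin-binding villin gene VLN3 (31), AT3G11130 (31), the calcium pump gene ACA10 (31) and AT4G01860 (27). With ssRNase they were LTI78 (9 sites, chromosome 5, 21240849 to 21243613), a cold- and drought-induced gene, AT2G30600 (9), BGAL1 (9), ARF1 (8), PEN3 (8), NADP-ME2 (8), the jasmonate repressor gene TIFY7 (6), the calcium sensor gene CBL1 (6), ERD4 (6) and AT1G78070 (6). All 10 dsRNase genes lie on the minus strand and all 10 ssRNase genes on the plus strand. Across the lists, 71.3% ± 0.63 of dsRNase PPSs (SD, n = 2) and 42.3% ± 0.88 of ssRNase PPSs (SD, n = 2) were on the minus strand, although the genes were split almost evenly.

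**Figure D1:**
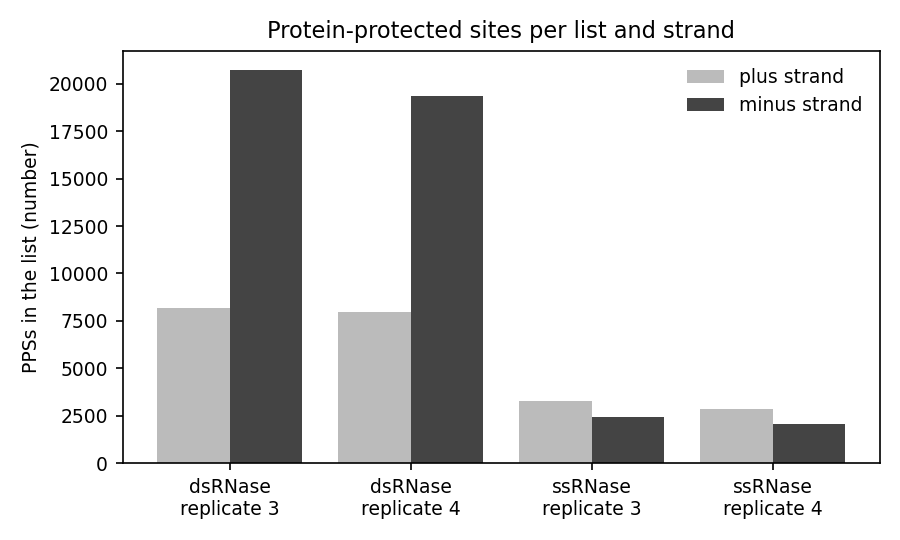
Number of PPSs (vertical axis) on the plus and minus strands in each of the 4 lists. Both dsRNase lists hold more minus-strand sites, 20706 and 19352, and both ssRNase lists hold more plus-strand sites, 3260 and 2873.

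The transgene parts and controls were checked by name. RANGAP1, whose targeting domain is used in the tag, had 2 dsRNase PPSs covering 98 nt in replicate 3 and 0 in replicate 4. UBQ10, whose promoter drives the tag, had 13 and 7 dsRNase PPSs, and ACT2, whose promoter drives the biotin ligase, had 4 and 5. RANGAP1 and UBQ10 have no known strand here, so their counts can include antisense sites. GRP7, a clock-regulated RNA-binding protein gene, had 3 and 3 dsRNase and 2 and 2 ssRNase PPSs, and its merged sites covered 1049 nt. Of the 5 longest merged PPSs, 2 lay in no listed gene: 2703 nt on chromosome 1 (29804716 to 29807418) and 2233 nt on chromosome 4 (2990325 to 2992557). The others lay in CT-BMY, a chloroplast beta-amylase gene (1450 nt), PYK10, a beta-glucosidase gene of endoplasmic reticulum bodies (1443 nt), and the polyubiquitin gene UBQ11 (1201 nt).

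Agreement of the calls was measured by overlap. Of dsRNase PPSs in genes, 61.1% in replicate 3 and 61.5% in replicate 4 were overlapped by the other replicate. The mean was 61.3%, against 31.7% after rotation. For ssRNase the shares were 38.3% and 47.0%, with a mean of 42.7% against 9.47%. Both directions compare the same pair of lists, so they give no spread between replicates. Between the RNases, 48.3% of ssRNase PPSs were overlapped by a dsRNase PPS of the same replicate number, against 29.2% rotated, and 9.05% of dsRNase PPSs by an ssRNase PPS, against 5.51%. The excess over rotation was 1.66-fold and 1.64-fold between the RNases, against 1.93-fold (dsRNase) and 4.51-fold (ssRNase) between replicates. Each exceeded all rotations (permutation p by rotation = 0.0198, the smallest possible). Of the merged sites, 54.4% came from 1 list only and 2.60% from all 4.

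Where along transcripts the protected nucleotides lay was asked in the 1462 genes with known exons. Of these, 593 and 590 had dsRNase PPSs in replicates 3 and 4, and 217 and 180 had ssRNase PPSs (336 and 283 sites). Coding sequence held 75.4% of dsRNase PPS nucleotides against 54.4% expected (log2 ratio 0.47 ± 0.01, SD, n = 2) and 70.1% of ssRNase nucleotides against 53.5% (0.39 ± 0.13, SD, n = 2). The 5' UTRs were depleted, at -1.19 ± 0.09 with dsRNase and -2.77 ± 0.04 with ssRNase. The 3' UTRs were at -0.89 ± 0.02 and -4.52 ± 0.68. The ssRNase UTR values rest on few nucleotides, 342 and 252 in 5' UTRs and 128 and 181 in 3' UTRs. Introns were depleted with dsRNase (-0.79 ± 0.05), while with ssRNase they stood at 0.35 ± 0.30 and did not pass in both lists (largest permutation p by rotation = 0.535). All other enrichments and depletions had a permutation p by rotation of 0.0198 in both lists. In ssRNase introns replicate 3 alone passed, at 0.56. Rotation spreads sites evenly over a transcript, while PPSs can be called only where there are reads, so uneven coverage can contribute to these values. With rotation over scored positions only, an alternative added after the data were seen, dsRNase stood at 0.39 in coding sequence, -0.86 in 5' UTRs, -0.83 in 3' UTRs and -0.74 in introns. For ssRNase the first 3 were 0.32, -2.43 and -4.49.

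The RNases differed most in the 3' UTR, by 3.63 (dsRNase minus ssRNase, log2), followed by the 5' UTR at 1.58 and introns at -1.13. Coding sequence differed by 0.08. The exact permutation p was 0.333 for the first 3, which is the smallest that 2 lists against 2 allow, and 0.667 for coding sequence, so no difference between RNases could pass this exact test. The size of the UTR differences depended on the genes and lists used. The spans below were added after the data were seen. Over all genes with a known strand, with introns counted in the span of each part, the 3' UTR spans were at -1.19 ± 0.04 with dsRNase and -3.01 ± 0.23 with ssRNase (SD, n = 2), a difference of 1.82, and the 5' UTR spans differed by 0.47. In the merged list ssRNase sites stood at -2.50 in 3' UTRs, a difference of 1.53. Over the whole merged list, 4749 sites join PPSs of both RNases and 2984 come from ssRNase lists only. The joined sites count for both RNases, so part of this smaller difference is built in.

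**Figure D2:**
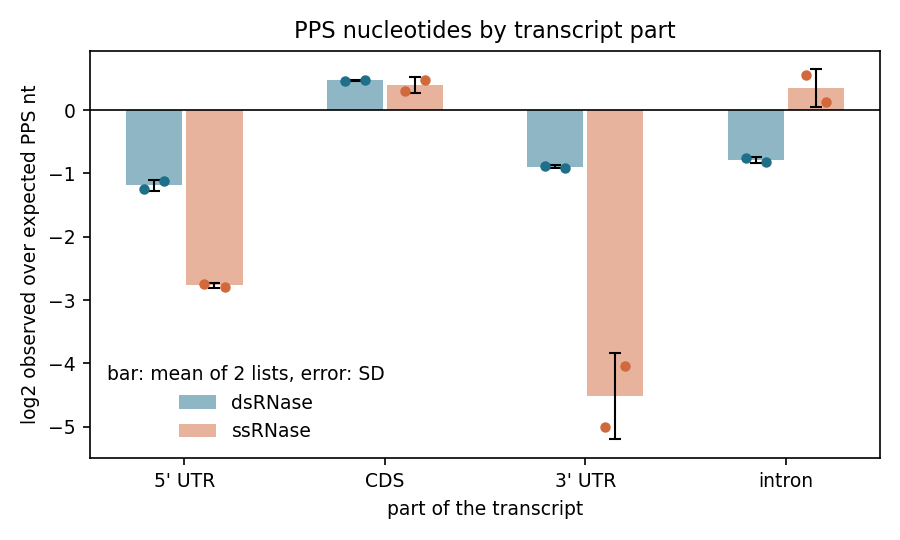
Log2 of observed over expected PPS nucleotides (vertical axis) in each transcript part for the dsRNase and ssRNase lists. Bars are means of 2 lists, points single lists and error bars SD. Coding sequence lies above 0 for both RNases and 3' UTRs reach -4.52 with ssRNase.

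PPS coverage at fixed landmarks was compared with rotated positions. Here all genes with a known strand and a PPS in the list were used, 5016 and 5046 with dsRNase and 2147 and 2128 with ssRNase. Splice sites were those of first and last constitutive introns, not of all introns. Start codon windows were covered more than rotated positions with dsRNase (log2 0.39 ± 0.04, SD, n = 2) and less with ssRNase (-0.70 ± 0.08). Stop codon windows were depleted with both, at -0.29 ± 0.04 and -1.62 ± 0.46. Splice donors were enriched at 0.26 ± 0.01 and 0.93 ± 0.05, and splice acceptors at 0.55 ± 0.03 and 0.64 ± 0.30. Transcript ends were depleted at -3.10 ± 0.53 and -4.58 ± 0.81, where read loss at the ends can contribute. Each landmark had a permutation p by rotation of 0.0198 in both lists. Uneven coverage can contribute to all of these values, as for transcript parts.

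Structure scores differed between the parts of mature mRNAs. Reading a high score as more folded RNA follows the naming of reads in the files, and would turn if that naming were exchanged. Mean scores were 0.48 in 5' UTRs, 0.20 in coding sequence and 0.36 in 3' UTRs. Coding sequence was lower than the 5' UTR of the same transcript by a mean difference of -0.28 (interval -0.31 to -0.26) over 9241 transcripts, and lower than the 3' UTR by -0.16 (-0.18 to -0.14) over 9448. Last exons exceeded last introns by a mean of 0.14 (0.12 to 0.17), but the median was 0.02 and 50.7% of transcripts were above 0.

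Scores dipped at the start codon, where the window differed by -0.20 (-0.23 to -0.17) from its surroundings over 6383 transcripts, and at splice acceptors (-0.15, -0.16 to -0.13). They were higher at splice donors (0.06, 0.05 to 0.08), by 0.13 with windows of 10 nt and 0.04 with the median over positions. Donors and acceptors here too were those of first and last constitutive introns. At stop codons the window exceeded its surroundings by 0.11 (0.09 to 0.14). The mean score climbed from -0.03 at 100 nt upstream to 0.33 at the stop codon and to a maximum of 0.42 at 17 nt downstream. The downstream side averaged 0.35. At the cleavage site the difference was 0.01 with an interval that includes 0 (-0.01 to 0.04). With the median over positions it was -0.06 and called.

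**Figure D3:**
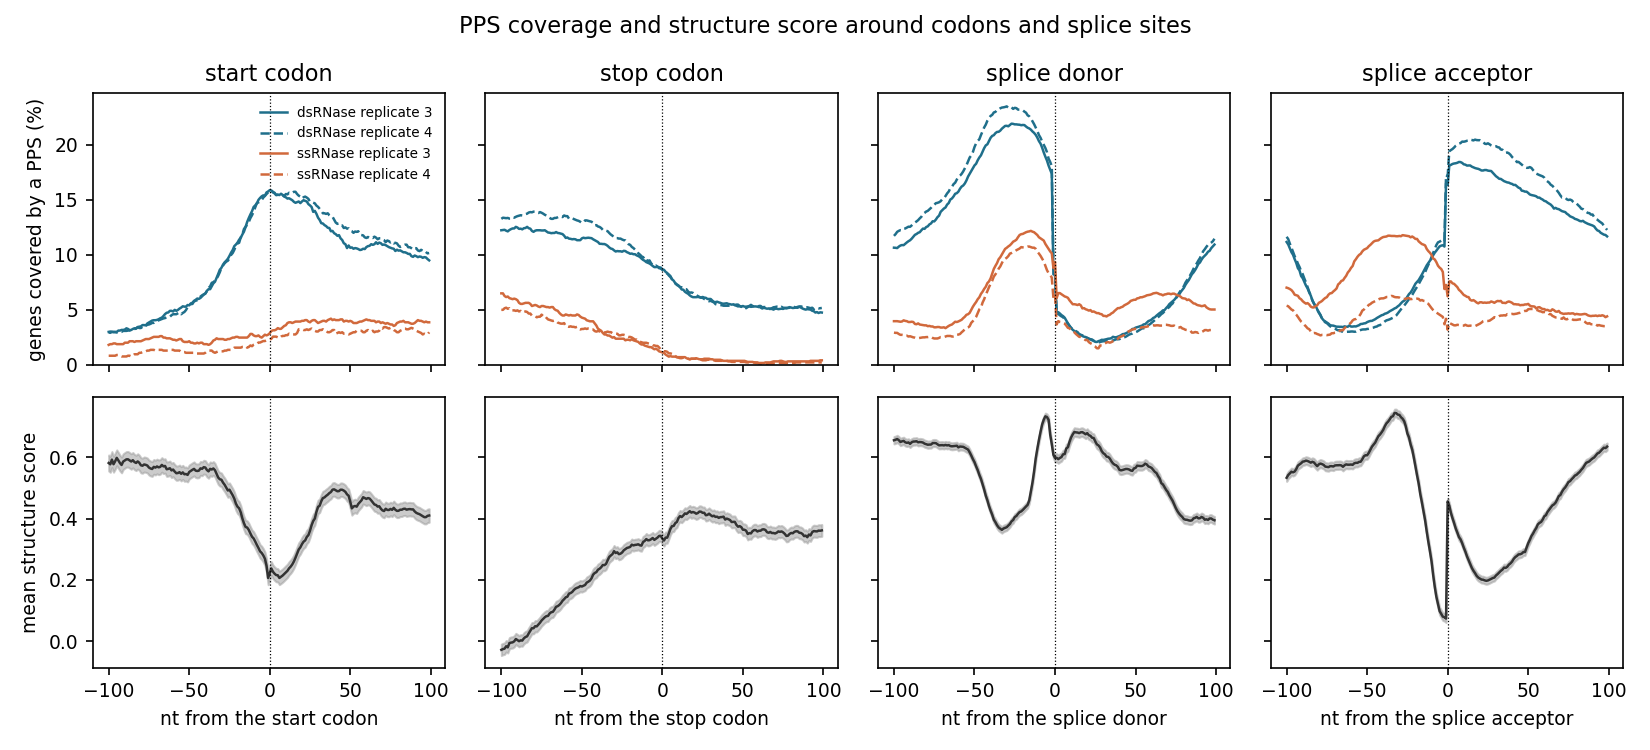
Share of sites covered by a PPS in percent (upper row) and mean structure score with standard error (lower row) against the distance in nt from start codons, stop codons, splice donors and splice acceptors. Lines in the upper row are the 4 lists. Splice sites are those of first and last constitutive introns. In the acceptor panel the score has its minimum of 0.07 just upstream of the site.

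The mature mRNAs with the highest mean scores were those of the ferredoxin gene FD1 (1.96), ADT4 (1.90), GASA4 (1.89), AT5G09480 (1.88), bZIP6 (1.87), EXL4 (1.84), MAT3 (1.78), AT4G38080 (1.78), AT1G80570 (1.73) and GN (1.73), a regulator of vesicle traffic. The lowest were AT3G23450 (-3.77), AT5G43570 (-2.76), MAP18 (-2.66), a microtubule-associated protein gene, GRP5 (-2.41), AT4G22000 (-2.30), AT1G47970 (-2.29), GRP23 (-2.19), AT1G56660 (-1.98), AT5G23760 (-1.90) and AT1G12080 (-1.89). The mean over 9543 mature mRNAs was 0.26 ± 0.54 (SD between mRNAs). Several of the named mRNAs lay near the floor of 100 reads, where extreme scores are less certain. Reads named double-stranded and single-stranded were 83 and 18 in AT5G09480, 17 and 86 in AT4G22000, and 8 and 105 in AT5G43570. The median was 424 reads. Others were deeply read, such as AT3G23450 with 447.7 and 8429.6.

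Protected sites had lower scores than their flanks. Mature scores could be used only for sites wholly in exons of the genes with known exons. In mature mRNAs 1763 such merged PPSs differed from their flanks by -0.40 (interval -0.45 to -0.35), and in primary mRNAs 31966 differed by -0.47 (-0.49 to -0.46). The ssRNase lists showed the wider gap, -1.47 ± 0.03 (SD, n = 2) in mature and -0.99 ± 0.16 in primary mRNAs. The mature value rests on 171 and 169 ssRNase sites in 124 and 116 genes. Flanks of these sites averaged -0.78, against 0.20 in primary mRNAs, so they may not represent the full lists. Calls and scores share the protein-removed libraries, so part of the ssRNase gap may come from how the sites were called. The dsRNase lists gave -0.18 ± 0.17 and -0.29 ± 0.16, and in primary mRNAs the 6338 plus-strand sites of replicate 3 showed no gap (-0.01, interval -0.03 to 0.01). In mature mRNAs dsRNase replicate 3 gave -0.06 (-0.11 to -0.005), with a permutation p by rotation of 0.0594, so its call rests on the interval alone, and replicate 4 gave -0.30 (p = 0.0198). With sites found in both replicates and with the better-scoring sites, replicate 3 lost its call, at -0.02 (-0.08 to 0.04) and -0.05 (-0.12 to 0.01). The second value was close to the -0.06 of all sites, with fewer sites (788 against 1453). Replicate 4 kept its call at -0.23 (-0.30 to -0.16) and -0.30 (-0.38 to -0.22).

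**Figure D4:**
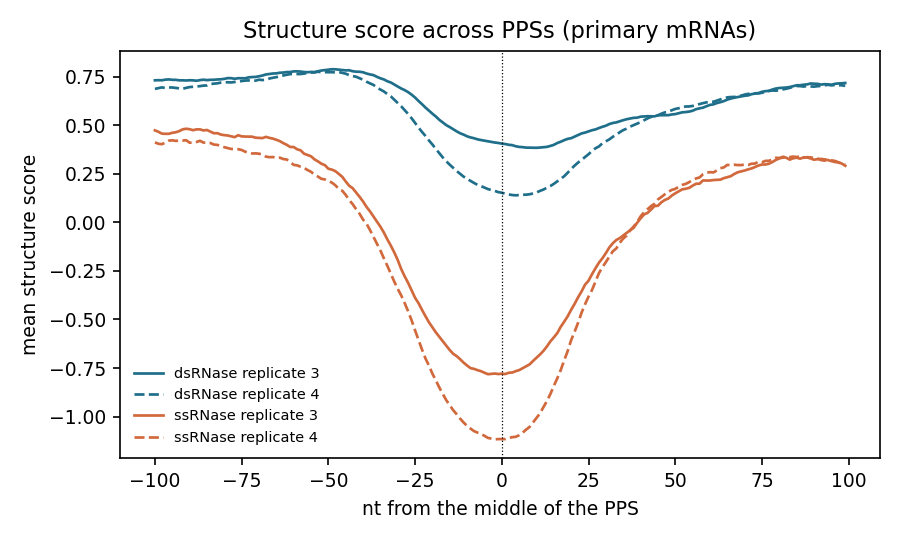
Mean structure score (vertical axis) against distance in nt from the middle of the PPS, in primary mRNAs, for the 4 lists. All 4 lines dip inside the sites, by a mean of -0.99 for ssRNase and -0.29 for dsRNase relative to flanks.

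The fixed gene lists were compared for PPS load. Photosynthesis genes carried few protected nucleotides for their length and depth: 22 of 25 measured members had a merged PPS, but the median was 180.0 nt per kb against 614.1 in matched random lists (adjusted p = 0.002, from 10000 random lists). Over all 9554 genes the median was 34.9 nt per kb. LHCB2.1 (1024 nt) and LHCA1 (936 nt), light-harvesting protein genes, had the most. The 11 minus-strand members ranged from 271.8 (RBCS2B) to 930.1 nt per kb (LHCB2.1). Plus-strand members reached at most 180.0 (LHCB4.1), and those without a known strand 196.2 (LHB1B2). With random lists matched on strand as well, an alternative added after the data were seen, their median was 631.9 (percentile 0, adjusted p = 0.002). The list was also low in each dsRNase list (adjusted p = 0.016 and 0.002), while with ssRNase adjusted p was 0.093 and 0.42. The same transcripts had high structure scores, with a median mean score of 1.28, and when random lists were matched on structure score and depth the call was lost (percentile 18.955, adjusted p = 0.93, an alternative added after the data were seen). That match leaves out length. Depth alone gave a random median of 393.6 nt per kb (percentile 0.14, adjusted p = 0.03). In 5 bins each of length and depth, random lists had a median of 521.8 nt per kb (percentile 0, adjusted p = 0.002), and with 5 bins of structure score added 408.5 (percentile 0.42, adjusted p = 0.096), all also added after the data were seen.

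None of the other 9 lists passed in the merged list. All 9 measured touch, wounding and early stress genes had a PPS, with a median of 765.0 nt per kb against 613.0 (adjusted p = 0.69; 364.6 and adjusted p = 0.072 when matched on structure score and depth), led by WRKY40 (1232 nt) and JAZ1 (1178 nt). All 19 measured SR splicing factor genes had one, led by RS40 (1544 nt) and SR30 (1005 nt), with 204.8 against 237.9 (adjusted p = 0.89). Other splicing and nuclear RNA-binding protein genes had 10 of 12, led by ATU2AF65A (1448 nt) and U1-70K (1078 nt), and passed only in ssRNase replicate 4 (adjusted p = 0.022). Clock genes had 11 of 13, led by PRR7 (2741 nt) and GI (1949 nt), and flowering genes 9 of 9, led by FCA (1201 nt) and FPA (1156 nt). Housekeeping genes had 8 of 11, led by UBQ10 (1119 nt) and GAPC2 (684 nt), with adjusted p = 0.35. RNA silencing genes had 6 of 13, led by AGO1 (1777 nt) and DCL1 (1302 nt), heat shock genes 4 of 7, led by DREB2A (1236 nt) and HSC70-1 (447 nt), and histone H3 and H4 genes 3 of 7, led by AT4G40040 (720 nt) and AT4G40030 (335 nt). Of the phosphate-starvation noncoding RNAs, AT5G03545 alone was measured and had 0 PPSs.

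**Figure D5:**
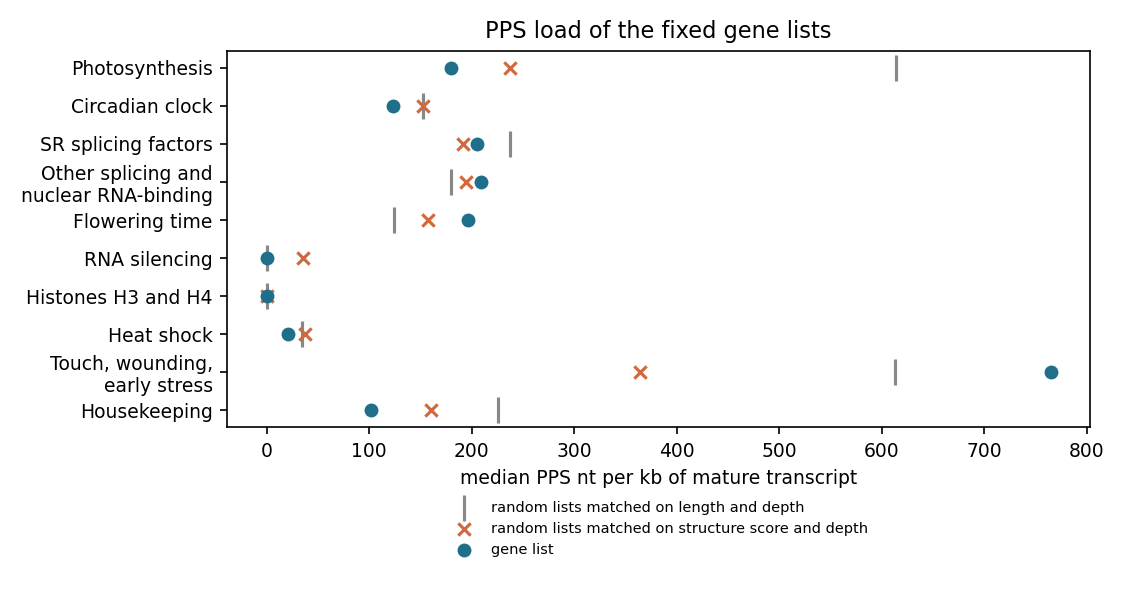
Median PPS nucleotides per kb of mature transcript (horizontal axis) for each gene list, beside the median of random lists matched on length and depth and of those matched on structure score and depth. Photosynthesis lies at 180.0 against 614.1 and 237.0.

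Splicing was compared between first and last introns of 16545 nuclear genes. The planned median difference in log2 of unspliced over spliced reads, last minus first, was 0 with an interval of 0 to 0, and was not called. Most introns had few reads, and 37.3% of genes had a difference of exactly 0. Summed over genes, unspliced reads were 34.05% ± 1.04 of reads on first introns and 37.4% ± 1.84 on last introns (SD, n = 2), a difference of 3.90 percentage points in replicate 1 and 2.77 in replicate 2. The mean over genes, added after the median was seen, was 0.07 (0.05 to 0.09). edgeR's quasi-likelihood test called 0 of 2585 genes after Benjamini-Hochberg adjustment (145 at an unadjusted p under 0.05), while DESeq2 called 4 and edgeR with TMM scaling 13.

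First introns with the highest unspliced ratio were in AT2G07708 (15 and 24 unspliced reads in replicates 1 and 2, and 0 spliced), ROC3 (a cyclophilin gene), ADC2 (an arginine decarboxylase gene), and the ubiquitin-conjugating enzyme genes UBC16 and UBC28. AT2G07708, ROC3 and ADC2 also led the last introns, because their first and last introns are the same, followed by AT1G23030 and AT2G33830. The last intron was less spliced than the first by the widest margin in AT2G18090 (6.68, log2), AT3G06670, AT2G25970, AT5G05010 and AT3G24880. The opposite was widest in UBC28 (-6.87), AT2G44090, AT3G53990, UBC16 and AT4G38350. These genes were picked for size, and none was called by edgeR with 1 library size per replicate. With TMM scaling, UBC28, UBC16, AT2G18090 and AT3G53990 were among the 13 called.

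Introns with a PPS were set against those without. Among 20444 introns with reads, the median log2 ratio of unspliced to spliced reads was -0.42 in 3258 introns with a merged PPS and -0.58 in 17186 without, a difference of 0.17 (permutation p = 0.0002, the smallest possible). Summed reads were 41.0% and 35.4% unspliced. The result depended on the summary: the difference of means was 0.03 (permutation p = 0.26), and with introns without reads included the difference of medians turned to -0.14. Introns with a PPS also had more reads, a median of 6 against 2. With permutations matched on read number too, an alternative added after the data were seen, both differences passed (permutation p = 0.0002), since the mean difference then expected was -0.26. Protected nucleotides of an intron can be called only from RNA that still holds the intron. Less spliced introns may therefore be easier to call, and matching on total reads does not remove this.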

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

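The strand tests on gene length, depth and the most protected genes, and all the photosynthesis tests but the last, were written down before their results were seen; the remaining tests below were chosen after the values they use had been seen. The start codon and strand differences between the RNases rest on both lists of each RNase moving in opposite directions and were not tested.

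Protected sites leaned to opposite genome strands with the RNases. The ratio of PPSs in minus-strand over plus-strand genes was 2.54 for dsRNase and 0.75 for ssRNase (means of 2 lists). Longer or more deeply read genes on the minus strand were argued against, because the dsRNase ratio was still 2.51 or more after matching on length and depth. A few genes with very many sites were argued against for dsRNase too, because its ratio was 2.23 or more without the 1% of genes with most PPSs. These tests did not cover ssRNase. Its ratios in replicates 3 and 4 were 0.78 and 0.74 after matching on length and depth. Without the 1% of genes with most PPSs they moved closer to even, to 0.86 and 0.83. For ssRNase a few genes with many sites stay open as part of the lean. Calling or scaling the strands apart stays open, since without reads of the protein-bound libraries it cannot be told apart from a strand bias of the libraries. No biological explanation was tested, since the design has no group that separates the genome strands.

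Structure scores were lower inside PPSs than in their flanks. The calls and the scores share the protein-removed libraries, so chance low coverage there could lower or raise the score inside a site, in opposite directions for the RNases. All 4 lists were below their flanks with intervals that exclude 0 in primary mRNAs, which argues against it as the whole cause for both RNases, although the plus-strand sites of dsRNase replicate 3 showed no gap (-0.01, against -0.24 on the minus strand). For one RNase it stays open and cannot be told apart from less folded RNA being bound, because the headers do not say which RNase gave which reads. Reading the score as folding implies that reads named double-stranded are those left by ssRNase. The open RNase would then be ssRNase, whose wider gap (-0.99) lies in the direction that chance low coverage would give. Depth of the genes was argued against as the whole cause, since in the 16 depth bins with 50 or more PPSs the highest upper bound was -0.105, although the dsRNase gap shrank from -0.51 in the lowest to -0.12 in the highest depth bin of replicate 3 and from -0.61 to -0.35 in replicate 4.

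Photosynthesis genes carried few protected nucleotides for their length and depth, although their median of 180.0 nt per kb was above the 34.9 of all genes. Reads shared between near-identical copies were argued against as the whole cause, because the 11 members with whole read numbers lay at percentile 0.24 of matched lists, with a higher median of 323.4 nt per kb. Coarse matching on depth was argued against by a percentile of 0.03 among the 50 genes nearest in depth. Their high structure score stays open, since the list rose to percentile 18.955 when matched on structure score and depth without length, but lay at 0.42 with length, depth and score in 5 bins each, a test chosen after the first was seen. Whether structure limits protection or its detection was not tested. The lowest values lay in members on the plus strand or without a known strand, at most 196.2 nt per kb, against 271.8 or more on the minus strand. The list stayed low when random lists were matched on strand as well (631.9 nt per kb).

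Start codon windows were enriched for dsRNase PPSs (log2 0.39) and depleted for ssRNase PPSs (-0.70), which was not tested as a difference. Introns were depleted for dsRNase PPSs (-0.79) and at 0.35 for ssRNase PPSs, a difference of -1.13 with an exact permutation p of 0.333, the smallest possible.

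The nuclear RNA libraries held reads from organelle genes, outside the comparisons of the report and above the 3 reads that a count of 0 allows. First introns of plastid genes had 480 and 672 reads in replicates 1 and 2, and those of mitochondrial genes 216 and 258.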

How the results depend on the processing

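Of 286 alternative values for 52 results, 259 kept their direction and their side of the threshold, or moved by less than the spread. Alternatives on rotation over scored positions, spans, differences in the merged list, means, scaling, matching on strand, structure score, depth alone, wider bins or read number, reads per intron and single RNases were chosen after seeing the data. Where no cause is named below, the cause was not tested. Keeping the better-scoring sites left 14805.5 dsRNase and 2682.5 ssRNase PPSs per list by construction, and moved the difference between RNases to -0.012 in coding sequence, 4.27 in 3' UTRs and -0.86 in introns. With spans over all genes with a strand the difference between RNases was 0.47 in 5' UTRs, 1.82 in 3' UTRs and -0.072 in coding sequence, and with the merged list 0.68, 1.53 and, in introns, -0.90. Merged sites that join both RNases count for both, so the smaller differences in that list are partly built in. For structure at dsRNase PPSs (means of -0.18 with the better-scoring sites and -0.12 with sites found in both replicates, which leaves fewer sites) replicate 3 lost its call and replicate 4 kept it. Replicate 3 itself gave -0.05 with the better-scoring sites and -0.02 with sites found in both replicates, against -0.06 with all sites. Leaving out a replicate gave differences between RNases of 1.49 to 1.67 in 5' UTRs and 3.13 to 4.12 in 3' UTRs, and ssRNase enrichment in introns of 0.13 to 0.56. At the cleavage site the structure difference turned to -0.057 with the median over positions. The photosynthesis list moved to percentile 18.955 when matched on structure score and depth without length, and to 0.42 with length kept in wider bins, where adjusted p was 0.096. First against last introns gave 0.072 with the mean over genes, 13 calls with edgeR and TMM and 4 with DESeq2, against a median of 0 and 0 calls. For introns with a PPS, the difference of means was 0.031 and the median over all introns, also those without reads, turned to -0.14, since introns without reads count as 0; for ssRNase sites it was then 0. With the replicate block, the paired difference between RNases in introns was -1.13 as without it, and 2 pairs cannot show whether the numbers pair the samples. Left out as not run were hexamers, parts by any transcript model, structure of mature mRNA parts outside PPSs, and edgeR with a replicate left out, which has no residual degrees of freedom. PPSs were mostly detected in deeply read genes, and a median of 3 reads per intron limits calls on single introns.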

Other observations

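The comparison of structure scores between gene lists was chosen after the data were seen, with random lists matched on length and depth and Benjamini-Hochberg adjustment over 10 lists. SR splicing factor mRNAs had the lowest scores, with a median mean score of -0.57 over 19 genes against 0.13 in random lists (adjusted p = 0.001, from 10000 random lists), among them RS40 (-0.85), RS31 (-0.80) and SR30 (-0.73). Other splicing and nuclear RNA-binding protein mRNAs were also low at -0.27 over 12 genes against 0.16 (adjusted p = 0.047), led by GRP7 (-1.68) and its relative CCR1 (-1.63). Photosynthesis mRNAs stood at the other end, at 1.28 over 25 genes against 0.20 (adjusted p = 0.001), and housekeeping mRNAs were high at 0.77 over 11 genes against 0.19 (adjusted p = 0.0073). Genes are not replicates, the scores are pooled over libraries, and reading them as folding follows the files' naming of reads.

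Introns covered by ssRNase sites had a higher share of unspliced reads in a comparison added after the data were seen. Among introns with at least 1 read, in 1147 such introns 47.0% of summed reads were unspliced, against 35.7% in the 19297 introns without one, and the difference of medians was 0.58 (permutation p = 0.0002, the smallest possible). The median number of reads was 7 against 2, and with permutations matched on read number too the difference still passed (permutation p = 0.0002). With introns without reads included both medians were 0 and the difference of medians was gone, while the difference of means was 0.12 (permutation p = 0.0004). Because a site in an intron can be called only from RNA that holds the intron, a higher unspliced share can itself favour a call. Matching on total reads cannot separate this from an effect of protection.

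Genes shared PPSs between RNases: 1317 genes had PPSs in both replicates of both RNases, against 542.3 if the gene sets were independent, though both depend on read depth.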
